A study of Mus musculus with 6 samples.

How the data were processed

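Promoter-capture Micro-C was made from E14 mouse embryonic stem cells 48 h after transfection with esiRNA, a pool of short RNAs cut by an endoribonuclease, against EGFP (Control), Smarca4, which encodes Brg1 (Brg1KD), or Ino80 (Ino80KD). Per the labels' protocols, chromatin was fixed with DSG and formaldehyde, cut with micrococcal nuclease, ligated and enriched for promoter fragments. There were 3 groups of 2 libraries. The labels put replicate 1 of every group in batch 1, Control replicate 2 in batch 2, and replicate 2 of both depletions in batch 3. Nothing in the labels says that replicates came from separate cultures, so the spread between them may be technical. RNA was not measured in these libraries, so the extent of each knockdown was not checked here.

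The authors deposited a list of loops per library, each a baited promoter fragment, another end and an interaction score, listed from a score of 5 up. The caller is not given in the sources used here. That score is the authors' own and was used only within a list. The authors also deposited 1 list of positions per group. These group lists held the loops of either replicate, except those of 1 bait (chromosome 2, 98661117 to 98662976), whose loops are in some values here and not in others. The total number of loops of a library, its number of intrachromosomal loops, its median span and its share of loops between baits include that bait. The interchromosomal counts, the overlaps and union of lists, the numbers of loops by the libraries listing them, the counts and values per 1000 at gene lists and the share near gene ends leave it out. Per the submitters' processing notes the build was mm10 and bedtools was used. The authors deposited a comparison table for each depletion against Control, with per the file headers a mean normalized signal over libraries, a log2 fold change with its error, a statistic, which is a score equal to the fold change over its error, and p-values before and after adjustment. Rows are intrachromosomal, and the regions of a bait can overlap and share contacts. No header states the direction of the fold changes. Loops listed only in both Brg1KD libraries had a deposited log2 fold change above 0 in 83.1% of cases and loops listed only in both Control libraries in 17.2%, and for Ino80KD these were 86.8% and 15.6%, so values above 0 are taken as higher after depletion.

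The design fixed before the data were examined was a test of contact counts per library. The files used here give no such counts, and the depth per library is unknown. As that design laid down for this case, the authors' deposited fold changes and p-values are described, and no test across libraries is used for loops, promoters or gene lists. After the data were seen, linear models with limma and its gene set tests fry and camera were run on the log2 scores across libraries under several settings, then set aside, because scores of separately called lists are not on a common scale and a loop under the minimum has no value. Those fits called few or no loops and promoters, the number changing with the setting. With camera's preset correlation the histone list was called in Brg1KD against Control, and the histone and developmental lists between the depletions, where fry called them too. Fry's test for changes in either direction called further lists. No list was called with an estimated correlation. These results had been seen when the comparisons with random bait sets were made. None of this is used below.

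Baits were named from the RefSeq genes of GRCm38.p6, whose primary chromosomes are those of mm10: by protein-coding genes with an end on the bait, then within 2 kb, then holding the bait. The annotation used here has no strand, so a promoter and a gene's far end are not told apart. Of 19083 baits, 12043 had a gene end on the bait, 1238 within the window, 4274 lay inside a gene, 721 met only another RNA gene and 807 stayed unnamed. Loops of 2 lists were called shared where both ends lay within 5 kb. The union of lists, the numbers of loops by the libraries listing them, and loops in some libraries only were counted by identical ends. Library values were compared with exact two-sided permutation tests, which with 2 against 2 libraries cannot go below p = 0.33. Shares of loops have 95% Wilson intervals, which cover counting error only.

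For each of 15 gene lists fixed before the data were examined, loops with at least 1 end on a bait of the list were counted per 1000 intrachromosomal loops. In the authors' deposited tables the rows of a bait were averaged with inverse squared errors as weights, and the median over a list's baits was placed among 10000 random bait sets matched on signal and span, and among 10000 sets that kept the list's pattern of neighbouring baits. The second kind allows for clusters. Both describe these libraries and carry no replicate error. They were chosen after seeing the data, as were the alternatives for the lists that the closing part gives. Tested on simulated data, in which values were permuted over baits so that neighbours were unrelated, 7 of 100 unshifted lists of 20 baits fell outside both kinds of set for Brg1KD and 4 for Ino80KD. With a shift of 0.1 on the log2 scale 45 and 34 did, and with 0.3 all 100 in both. Named loops are, as fixed beforehand, those with the smallest p-values, 10 per direction, since none passed, with 8 chosen genes and up to 4 members per list, and a part of them is named here. The fixed minimum of 20 mean normalized contacts, which concerns the named loops alone, could be set only against the mean over libraries. It was not used to filter them. For list members and the chosen genes, which often have several entries, the mean over a gene's entries is given, weighted by inverse squared errors. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.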

Results

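Contacts of baited promoters were mapped in mouse embryonic stem cells depleted of Brg1, the ATPase of the esBAF chromatin remodeller, or of Ino80, the ATPase of the INO80 remodeller, to ask how each affects promoter interactions. There were 2 libraries per group. The lists held 19045 and 18220 loops in the Control libraries, 17567 and 16585 in Brg1KD, and 18611 and 17673 in Ino80KD, with the bait that the group lists lack included. Counted by identical ends, most intrachromosomal loops were listed in a single library. Of 49634 in the union of the lists, 33773 were in 1 library and 1546 in all 6. Within 5 kb, 49.8% ± 0.689 (SD, n = 2) of a Control library's loops were in the other Control list, 46.0% ± 0.987 in Brg1KD and 50.9% ± 1.27 in Ino80KD. Of the pooled Control loops, 51.3% were in the Brg1KD list and 54.5% in the Ino80KD list, and 54.6% of Brg1KD loops were in the Ino80KD list. The pooled lists join 2 libraries and are longer, so these shares cannot be set against those between single libraries. A Control library's loops were found at 42.8% to 45.6% in a Brg1KD library and 46.1% to 51.8% in an Ino80KD library. A Brg1KD library's loops were found at 48.7% to 52.0% in a Control library, whose list is longer. A loop that is not listed scored under the authors' minimum and is not shown to be absent.

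After Brg1 depletion fewer intrachromosomal loops were listed, and those at histone gene clusters and developmental regulators made up a smaller share of the total. Brg1KD libraries held 12672.5 ± 508 (SD, n = 2) such loops against 14918 ± 660 in Control, with that bait included here and left out of the values per 1000. At histone genes, most of which supply histones in S phase, 67 and 84 loops were listed against 176 and 117 in Control, or 5.97 ± 0.716 per 1000 loops against 9.81 ± 2.37 (SD, n = 2). At developmental regulators, transcription factor and signalling genes of the early embryo, 50 and 52 loops were listed against 108 and 84, or 4.05 ± 0.0485 per 1000 against 6.44 ± 0.858. For each of these measures both Brg1KD libraries lay below both Control libraries, and for the number of intrachromosomal loops the exact permutation p was 0.33, the smallest that this design allows. Loops between baits made up 3.12% ± 0.472 of the intrachromosomal loops, that bait included, against 3.98% ± 0.639 (SD, n = 2, exact permutation p = 0.33).

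Within batch 1, which holds 1 library per group, there were 12313 intrachromosomal loops in Brg1KD and 15385 in Control, that bait included, and 12254 and 15322 without it. The histone value there was 5.47 per 1000 (95% Wilson interval 4.31 to 6.94) in Brg1KD and 11.5 (9.92 to 13.3) in Control, a ratio of 0.476. The developmental value was 4.08 (3.10 to 5.37) against 7.05 (5.84 to 8.50), a ratio of 0.579. These intervals cover counting error only, and for histone clusters those of the Control libraries did not overlap each other either (6.79 to 9.73 in Control replicate 2). Brg1KD replicate 1 also listed more interchromosomal loops than the other libraries, 3809 against 2720 in the Control library of its batch with that bait left out, and without it the ratios were 0.661 and 0.623. The histone list's name pattern, fixed beforehand, also took in H13, which is not a histone gene, and histone genes outside the replication-dependent set such as H1f0 and H2az1. With replication-dependent names only, an alternative added after seeing the data, the ratio was 0.608.

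**Figure D1:**
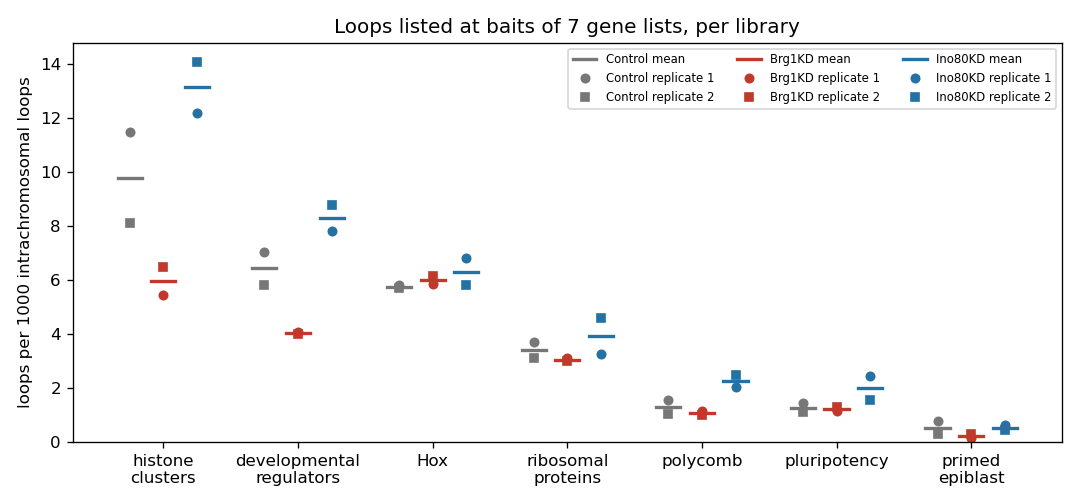
Loops per 1000 intrachromosomal loops (vertical axis) with an end on a bait of 7 gene lists (horizontal axis), with 1 point per library and a line at each group's mean. At histone clusters both Brg1KD libraries lie below both Control libraries, with means of 5.97 and 9.81.

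Among single contacts, the smallest p in the authors' deposited table for Brg1KD belonged to the promoter of Irx5, a homeodomain factor (chromosome 8, bait 92355025 to 92358535, a gene end on the bait). Its contact with a region from 91680001 to 91864750, which holds the bait of its neighbour Irx3, had in the authors' deposited table a log2 fold change of -0.81 ± 0.25 (SE). A loop between the baits of Irx5 and Irx3 was in both Control lists and both Ino80KD lists and in neither Brg1KD list. These listings come from the same libraries as the fold changes and are not separate support. Further lower values in the authors' deposited table were those of Rbmxl2, an RNA-binding protein gene, at -1.19 ± 0.37, Zic5, a zinc finger factor, at -0.74 ± 0.24, Hmgb2, a chromatin protein gene, at -0.89 ± 0.30, and Chd2, a chromatin remodeller gene, at -0.76 ± 0.27. Between the baits of Hmgb2 and the developmental regulator Hand2, looked up in the same way, every library listed 0 loops. Higher values in the authors' deposited table were those of Osbp2 at 0.50 ± 0.18 and Cd300ld3 at 0.63 ± 0.23. None of these passed the adjustment. Of 33243 entries in the authors' deposited table, 0 had an adjusted p under 0.05, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 the authors' deposited table had 275 lower and 124 higher entries, 1.20% of all, which is less than chance gives for a p-value that is evenly spread.

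By gene list, the median over baits of the log2 fold change in the authors' deposited table was -0.27 at histone clusters, below 0 at 32 of 38 baits and under all random bait sets of both kinds. The baits of that list form 7 runs of neighbours. With 1 value per 1 Mb block its median in the authors' deposited table was -0.21, below 0 in 8 of 9 blocks. Among its members, the weighted mean over a gene's entries in the authors' deposited table was -0.51 ± 0.17 for H2ac6 and -0.42 ± 0.21 for H4c4, with an SE that treats the entries of a gene as independent and is too small where their regions overlap, here and for the list members that follow. At markers of the primed epiblast the median in the authors' deposited table was -0.41, below 0 at 9 of 10 baits and likewise under all random sets, with Zic2 at -0.42 ± 0.18 and Lef1 at -0.48 ± 0.26. Few loops stood behind that list, 12 and 4 in Control and 2 and 4 in Brg1KD, a ratio per 1000 of 0.445 that was 0.849 without Control replicate 1, 0.301 without Control replicate 2, 0.308 without Brg1KD replicate 2, 0.208 within batch 1, and 0.268 with batch and group fitted over the 6 libraries. Ribosomal protein genes had a median of -0.13 in the authors' deposited table, at percentiles 0.270 and 0.400 of the matched and the neighbour-keeping sets. Developmental regulators had -0.10 in the authors' deposited table, at percentiles 1.78 and 0.750, with Pax9 at -0.47 ± 0.096 and Foxa2 at -0.19 ± 0.10. The place of that last list outside random sets was not kept in other units. With 1 value per gene its median in the authors' deposited table was -0.11, at percentile 3.56 of random gene lists, and with signal, span and gene density fitted it was -0.024, at percentile 26.8. The same fit to the authors' deposited table placed BAF subunits at 0.14 and Hox genes at 0.10, at percentiles 99.5 and 98.7 of random gene lists, which do not keep neighbours together.

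The other 11 lists lay inside at least 1 kind of random set. Their medians in the authors' deposited table were -0.097 for pluripotency genes, 0.066 for Hox genes, 0.074 for BAF subunits, 0.030 for INO80 subunits, -0.082 for polycomb genes and -0.053 for architecture genes. For the rest, the authors' deposited table gave 0.0069 for heat shock and stress genes, 0.034 for 2-cell-like genes, -0.056 for trophoblast markers, -0.15 for primitive endoderm markers and -0.086 for fibroblast feeder markers. In all, 4 of 15 lists lay outside both kinds of set with 1 value per bait, developmental regulators included. If the lists were random sets of baits, 0.75 would lie outside a single kind. That number allows for no difference between unchanged libraries at whole lists, and some lists share genes. An excess over it is thus not shown to be beyond chance between libraries.

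After Ino80 depletion the number of intrachromosomal loops was close to Control, and more of them were listed at histone clusters and developmental regulators. Ino80KD libraries held 14462 ± 410 (SD, n = 2) loops, that bait included, against 14918 ± 660 in Control (exact permutation p = 0.667). Histone clusters had 179 and 199 loops, or 13.1 ± 1.35 per 1000 (SD, n = 2) against 9.81 ± 2.37 in Control, and developmental regulators 115 and 124, or 8.31 ± 0.672 against 6.44 ± 0.858. Polycomb genes, which encode subunits of repressive chromatin complexes, had 30 and 35 loops against 24 and 15, and pluripotency genes 36 and 22 against 22 and 16. Within batch 1 the ratios to Control were 1.06 for histone clusters, 1.11 for developmental regulators, 1.31 for polycomb genes and 1.71 for pluripotency genes, each with overlapping 95% Wilson intervals, and with 1 library per group the differences there were not tested. Ribosomal protein genes, at 1.15 times Control, turned to 0.879 within batch 1 and 0.965 with batch and group fitted over the 6 libraries.

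Among single contacts, the smallest p in the authors' deposited table for Ino80KD belonged to a bait inside Gata3, a developmental regulator (chromosome 2, 9880132 to 9882991). Its contact with a region from 10340001 to 10480000, which holds the bait of the polycomb-associated gene Sfmbt2, had in the authors' deposited table a log2 fold change of 1.22 ± 0.37 (SE). Loops between the baits of Gata3 and Sfmbt2 numbered 4 and 2 in Ino80KD, 1 and 0 in Control and 0 and 0 in Brg1KD. Further higher values in the authors' deposited table were those of Bahd1, a heterochromatin protein gene, at 0.63 ± 0.20, Radil at 0.56 ± 0.20 and Polrmt, the mitochondrial RNA polymerase gene, at 0.64 ± 0.23. Lower values in the authors' deposited table were those of Dhrs2 at -0.55 ± 0.20 and the olfactory receptor gene Olfr1134 at -0.55 ± 0.20. None of these passed the adjustment. Of 34774 entries in the authors' deposited table, 0 had an adjusted p under 0.05, and at an unadjusted p under 0.05 there were 317 higher and 133 lower entries, 1.29% of all.

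By gene list, 4 medians in the authors' deposited table for Ino80KD lay above both kinds of random set. They were those of polycomb genes at 0.19, histone clusters at 0.15, ribosomal protein genes at 0.13 and pluripotency genes at 0.11. With 1 value per 1 Mb block the histone median in the authors' deposited table was 0.092, below 0 in 3 of 10 blocks. Weighted means over a gene's entries in the authors' deposited table were 0.24 ± 0.10 for Pcgf2 and 0.21 ± 0.17 for Epop among polycomb genes, 0.21 ± 0.11 for Rpl41 among ribosomal protein genes, and 0.42 ± 0.14 for Stat3, which relays the LIF signal, among pluripotency genes. The other medians in the authors' deposited table were 0.065 for developmental regulators, where Nkx2-1 was at 0.35 ± 0.11, -0.054 for Hox genes, 0.057 for BAF subunits, 0.16 for INO80 subunits, 0.13 for architecture genes and 0.10 for heat shock and stress genes. For the remaining lists the authors' deposited table gave -0.018 for 2-cell-like genes, -0.028 for trophoblast markers, -0.090 for primitive endoderm markers, -0.034 for primed epiblast markers and -0.057 for fibroblast feeder markers. With signal, span and gene density fitted to the authors' deposited table, developmental regulators were at 0.12, at percentile 99.97 of random gene lists.

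**Figure D2:**
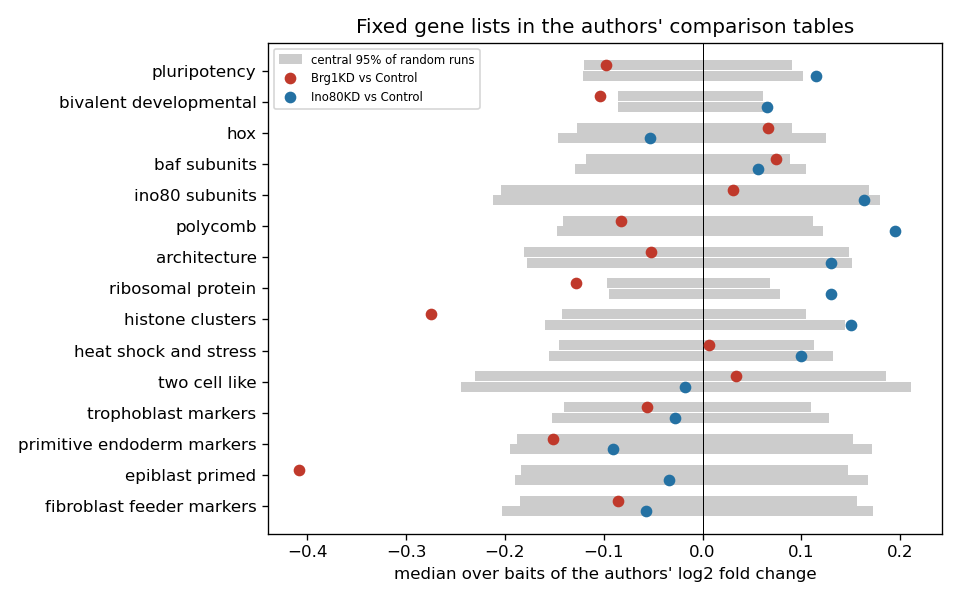
Median over baits of the authors' log2 fold change (horizontal axis) for 15 gene lists (vertical axis), as 1 point per depletion, with grey bars for the central 95% of random sets that keep the pattern of neighbouring baits. In the authors' deposited table histone clusters lie at -0.27 for Brg1KD and 0.15 for Ino80KD.

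Set against each other, Ino80KD libraries listed 2.20 times as many loops per 1000 at histone clusters as Brg1KD libraries, and 2.05 times as many at developmental regulators. This contrast is balanced for batch, since each depletion has 1 library in batch 1 and 1 in batch 3. Within these batches the ratios were 2.23 and 2.18 at histone clusters and 1.92 and 2.19 at developmental regulators. With 2 pairs the exact permutation of signs cannot give a p below 0.5. Over the 15 lists, 10 were higher in Ino80KD in both batches and 0 were lower in both. Subtracting the log2 fold changes of the authors' deposited table for Brg1KD from those for Ino80KD gave a median of 0.41 at histone clusters, above 0 at 33 of 36 baits. These baits form 6 runs of neighbours. With 1 value per 1 Mb block the median from the authors' deposited tables was 0.34, below 0 in 2 of 8 blocks. The difference between the authors' deposited tables was 0.36 at primed epiblast markers, 0.28 at polycomb genes, 0.23 at heat shock and stress genes, 0.22 at pluripotency genes, 0.17 at ribosomal protein genes, 0.16 at developmental regulators and -0.46 at 2-cell-like genes, and these 8 of 15 lists lay outside both kinds of random set. With signal, span and gene density fitted to the authors' deposited tables, 2-cell-like genes were at -0.21, at percentile 10.6 of random gene lists, and Hox genes at -0.15, at percentile 0.210. All of these are medians of differences per bait without replicate error, and with no counts per library no test of single contacts between the depletions is used. The sets of loops that follow were counted by identical ends. Intrachromosomal loops listed in both Ino80KD libraries and neither Brg1KD library numbered 1401, and 807 were in both Brg1KD libraries and neither Ino80KD library. Pairs of 1 library from each group gave 787 to 952 such loops. Against Control, 1341 loops were in both Control libraries only and 733 in both Brg1KD libraries only, with 704 to 1021 for mixed pairs. For Ino80KD these were 1086 and 983, with 819 to 1207. The Brg1KD lists were the shortest, at 12254 and 12962 loops without the bait that the group lists lack. Those of Ino80KD held 14675 and 14113, and those of Control 15322 and 14394. Longer lists can by length alone give more loops found in their group only, and the mixed pairs do not correct for that.

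The depletions shared their Control libraries. Over 23522 entries in both of the authors' deposited tables, log2 fold changes had a correlation of 0.335 across contacts, which are not independent, and a covariance of 0.0242. Unchanged groups simulated against shared controls gave 0.500 and 0.0422. Their variance was 0.0844 against 0.0705 and 0.0735 in the authors' deposited tables, so the simulated noise was larger than the observed spread. That raises the simulated covariance but not the correlation, since the simulation gave every library the same noise per contact. The observed correlation thus showed no agreement beyond that of shared controls in this simulation. At an unadjusted p under 0.05 in the authors' deposited tables, 1 entry was higher and 4 were lower after both depletions, where independent lists would share 0.374 and 1.43. With shared controls independence is not the value of unchanged groups, so part or all of this excess may come from them, and they could not be split.

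Of the genes chosen beforehand, Ino80 and Esrrb had no entry in the authors' deposited tables. The weighted mean over the entries of Smarca4 in the authors' deposited tables was 0.25 ± 0.081 (log2 fold change ± SE, entries taken as independent) over 6 entries in Brg1KD and 0.27 ± 0.10 over 3 in Ino80KD. Among pluripotency factor genes, Pou5f1 was in the authors' deposited tables at 0.0062 ± 0.12 over 7 entries in Brg1KD and 0.25 ± 0.11 over 8 in Ino80KD. For Nanog the authors' deposited tables gave -0.041 ± 0.13 over 3 entries and 0.20 ± 0.094 over 9. Sox2 was in the authors' deposited tables at -0.43 ± 0.34 in its 1 entry in Brg1KD and 0.14 ± 0.14 over 3 in Ino80KD, and Klf4 at -0.19 ± 0.45 and -0.059 ± 0.43 in 1 entry each. Myc had 1 entry in the authors' deposited table for Brg1KD, at 0.30 ± 0.42, and none for Ino80KD. The regions behind a gene's entries differ between the authors' deposited tables. No single entry of these genes passed the adjustment, and the smallest unadjusted p among them in the authors' deposited tables was 0.102.

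Median span of intrachromosomal loops, that bait included, was 265580 ± 22533 bp in Control, 240737 ± 28144 bp in Brg1KD (SD, n = 2, exact permutation p = 0.667) and 244638 ± 2596 bp in Ino80KD (exact permutation p = 0.33). In the authors' deposited table for Ino80KD the median log2 fold change went from 0.083 for regions under 50 kb from the bait to -0.057 over 500 kb. For Brg1KD the authors' deposited table gave -0.030 and -0.076, with 0.023 at 100 to 250 kb, so there was no steady fall with distance. A protein-coding gene end lay within 2 kb of the other end of 49.8% ± 1.21 of Control loops, 49.7% ± 1.66 of Brg1KD loops and 53.6% ± 1.24 of Ino80KD loops (SD, n = 2). Both Ino80KD libraries lay above both Control libraries in this share, and within batch 1 it was 52.7% against 50.7%.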

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

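All tests below were chosen after the ratios and counts they weigh had been seen. Brg1KD replicate 1 listed 3809 interchromosomal loops, outside the comparisons between groups, against 2720 and 2942 in Control. Brg1KD replicate 2 listed 2600, no more than Control, but its list was also the shortest, at 16585 loops in all. Intrachromosomal loops made up 70.1% and 78.6% of the Brg1KD lists, against 80.8% and 79.3% in Control. Those shares include the bait that the group lists lack, while the interchromosomal counts here leave it out. Without it, Brg1KD replicate 2 listed 12962 intrachromosomal loops beside its 2600 interchromosomal ones. The Control libraries listed 15322 beside 2720 and 14394 beside 2942. On that footing the share in Brg1KD replicate 2 lay between those of the Control libraries. In batch 3, which has no Control library, Ino80KD listed 2405 interchromosomal loops. The excess was thus seen in Brg1KD replicate 1 only, and 1 further Brg1KD library does not settle whether depletion is the cause. Of the interchromosomal loops in Brg1KD replicate 1, 64.3% were by identical ends in no other library, against 33.4% to 40.1% in the other 5. Ligation or calling noise in that library may account for them.

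Loops per 1000 at histone clusters were 2.20 times as frequent in Ino80KD as in Brg1KD, and at developmental regulators 2.05 times. Every Brg1KD library lay below and every Ino80KD library above both Control libraries. Tests on scores of the difference between the depletions were set aside, and none is used here. With ratios of 2.23 and 2.18 (histone) and 1.92 and 2.19 (developmental) within batches 1 and 3 that contrast is balanced for batch, but with 2 pairs the exact permutation of signs cannot go below p = 0.5. For Brg1KD, a proportional loss of loops would leave the ratio to Control inside that of random runs of baits with as many Control loops. Counted at the baited end, however, the ratio was 0.618 for histone clusters (random range 0.792 to 1.24) and 0.666 for developmental regulators (0.823 to 1.21). Of the lists not flagged, architecture genes at 0.449 (0.557 to 1.60) and primed epiblast markers at 0.445 (0.510 to 1.66) also lay below their range. They rest on 21 and 16 Control loops. The remaining lists lay inside it. Against Control, the ratios of 0.476 and 0.579 within batch 1 compare libraries of the same batch, but rest on 1 library per group. Those of 0.479 and 0.560 with batch and group fitted rest on the same single Control library. A difference between single libraries thus cannot be told apart from Brg1 depletion there. The Control libraries of batches 1 and 2 themselves differed at histone clusters, and batch and library cannot be separated in that difference. A change of these contacts with depletion is a hypothesis that may account for the values, and library depth, which is unknown, remains open for both depletions.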

How the results depend on the processing

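For changed contacts, no paired analysis was possible because the files used here give no contact counts. Against Control, only batch 1 is shared. With batch and group fitted over the 6 libraries (replicate block, added after seeing the data), where batch 3 enters through the other depletion and 1 residual degree of freedom is left, Brg1KD over Control was 0.479 at histone clusters, 0.560 at developmental regulators, 0.759 at ribosomal protein genes and 0.268 at primed epiblast markers. Ino80KD over Control was 1.06, 1.47, 1.42 and 0.965 at histone clusters, pluripotency, polycomb and ribosomal protein genes. The depletions share batches 1 and 3, and with pairing by batch (replicate block, added after seeing the data) Ino80KD over Brg1KD was 2.20 at histone clusters and 2.05 at developmental regulators, the same as without it. The block changed no call, as none that is used here rests on a fit across libraries. For lack of counts the planned normalizations, count tests, count filters, batch and span models, split controls and promoter tests were not run. The count of changed contacts was 0 in both tables at adjusted p under 0.01 and under 0.1, and, added later, after dividing statistics by their SD and with 1 value per bait. At an unadjusted p under 0.05, 5 contacts were shared in direction by the depletions. Identical ends gave 34.5%, 37.9% and 38.5% for Control in Brg1KD, Control in Ino80KD and Brg1KD in Ino80KD, and 10 kb gave 56.5%, 59.2% and 59.3%. The stronger part of each list gave 53.9% for the last. Between replicates, as means of both directions, identical ends gave 34.3%, 31.1% and 34.7% for Control, Brg1KD and Ino80KD, and 10 kb 54.7%, 50.9% and 56.1%. Gene ends within 1 kb gave 41.4%, 41.6% and 45.4%, and within 5 kb 58.3%, 58.8% and 62.1%. The windows set these shares by construction.

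Of the list medians, that of developmental regulators in Brg1KD was -0.024 with signal, span and gene density fitted, and those of histone clusters were -0.21 in Brg1KD and 0.092 in Ino80KD with 1 value per 1 Mb block. Ribosomal loops per 1000 in Ino80KD, 1.15 times Control, ranged from 0.955 to 1.35 without 1 library and were 0.879 in batch 1 and 0.965 with the block; the cause was not tested. Without Control replicate 1 the ratio at primed epiblast markers in Brg1KD was 0.849 in place of 0.445. With replication-dependent histone names only, added after seeing the data, the histone medians were -0.30 in Brg1KD and 0.16 in Ino80KD. Alternatives that kept their direction and moved less than the spread set for their result, or left a count of 0, numbered 135. Another 23 moved further and 3 reversed. These numbers do not measure robustness. For ratios of loops per 1000 the spread was the SDs of both groups, added, over the Control mean. Leaving out a depleted library cannot move a ratio that far. At primed epiblast markers the spread was 0.867, so 0.849 in place of 0.445 is among the 135. A count of 0 at adjusted p under 0.05 also fixes that under 0.01.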

Other observations

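The test of gene density was chosen before its result was seen, its bootstrap interval after, and the olfactory list after the data were seen. Loops that join histone baits to each other numbered 38 and 16 in Control, 5 and 14 in Brg1KD and 34 and 50 in Ino80KD. Loops that join developmental regulators to each other numbered 5 and 2 in Control, 0 and 0 in Brg1KD and 5 and 6 in Ino80KD. Genes of genome architecture, such as those of CTCF and cohesin, had 8 and 13 loops in Control, 5 and 3 in Brg1KD and 11 and 12 in Ino80KD. Trophoblast markers had 24 and 25 loops in Control, 11 and 19 in Brg1KD and 22 and 22 in Ino80KD. Hox genes had 89 and 82, 72 and 80, and 100 and 82 in the same order, a ratio per 1000 in Brg1KD of 1.05, beside 0.628 for developmental regulators.

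Olfactory and vomeronasal receptor baits, which lie in large clusters, had 57.8 ± 3.27 loops per 1000 in Ino80KD and 69.8 ± 9.60 in Control (SD, n = 2), with 66.4 ± 11.9 in Brg1KD.

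In the authors' deposited table for Ino80KD the median log2 fold change of regions under 50 kb lay 0.14 above that of regions over 500 kb. Gene density around the bait is a candidate explanation. With baits split into equal classes of low, middle and high density, the difference was 0.0756, 0.0779 and 0.113. The smallest has a bootstrap interval of 0.0398 to 0.107, which takes in the bound of 0.0702 set beforehand, so that test cannot decide. The other intervals were 0.0456 to 0.108 and 0.0682 to 0.163. A difference thus remained within each class, so density split in this way did not account for all of it. These intervals resample baits and carry no replicate error.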
